A study of Mus musculus with 2 samples.

How the data were processed

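Total RNA of gastrocnemius muscle from TECRLflox/flox and TECRLscko mice was sequenced as 1 library per group. Per the labels' protocols, RNA was extracted with a commercial total RNA kit, libraries were built with the VAHTS Universal V6 kit and sequenced on an Illumina NovaSeq, and library size was checked on an Agilent instrument. Per the submitters' processing notes, CASAVA, HISAT2 2.0.4, StringTie 1.3.0 and the mouse build GRCm38 were used, without a statement of which step each served. The read counter, its strand setting, the annotation release and the read filters are not given in the sources used here. Without a stated strand setting, reads of genes that overlap on opposite strands cannot be assigned with certainty, and the same holds for overlapping models on 1 strand and for near-identical copies.

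The deposited table holds, per the file headers, a raw count and an FPKM value for each gene in each library. The counts deposited by the authors are whole numbers with no normalization and sum to 19281017 in the control and 16946124 in the TECRLscko library. The deposited FPKM values were compared with the counts: the gene length they imply was equal in both libraries, within 1%, for 100% of 16041 genes, so that they are counts divided by a gene length and by the library's total over the table. That length equalled the summed length of all distinct annotated exons for 72.3% of 18043 genes, which overstates the length of genes with several overlapping exon versions and understates their FPKM. It cancels in ratios between libraries apart from the pseudocount and the filter. Of 34745 genes, 34344 have an identifier that is also in GENCODE M21 (GRCm38), and 27776 of those have identical coordinates. Gene classes, transcript lengths and GC content come from that annotation, and coordinates are printed as deposited. The 59 gene names on more than 1 line were kept apart by identifier.

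Counts were scaled with TMM factors (edgeR 4.0.16, R 4.3.3), 1.02 for the control and 0.977 for the TECRLscko library. The log2 ratio is log2 of TECRLscko CPM plus 0.5 over control CPM plus 0.5, which understates the difference of low genes; folds of single genes are plain CPM ratios without the pseudocount. Intervals of ratios are exact 95% Clopper-Pearson intervals conditional on the summed counts, and shares of counts have 95% Wilson intervals. Sequencing reads without molecular identifiers are not independent molecules, so intervals and the floor of 3 counts per library cover counting error only. The floor corresponds to 0.152 CPM in the control and 0.181 CPM in the TECRLscko library. Genes with a mean of at least 1 CPM were compared, and a gene was counted as higher or lower from 2-fold. No test across mice was possible with 1 library per group, and none was made.

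Before the data were examined, 45 gene lists were fixed for fiber types, metabolism, the cell types of muscle, immune cells, signaling and stress. For each list with at least 5 members past the filter, the median log2 ratio was ranked among 10000 random lists of the same size matched on mean expression in 20 bins, and a list under the 2.5 or over the 97.5 percentile is said to lie outside. This describes the 2 libraries and not the genotypes. The genes named in the text followed a rule fixed at the same time: Tecrl, Tecr, Pax7 and the Egr genes, the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 5 CPM and a name that is not a clone or predicted gene, up to 5 members of each described list with the greatest ratio or expression, and genes a closing observation is about. Some genes that the rule takes are not reported here. Members of a list named beyond that rule were chosen after their values were seen. The lists of cytokine feedback, STAT5-induced and STAT3-induced genes were added after the ratios had been seen.

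Alternatives fixed in advance were total-count scaling, DESeq2 1.42.0 size factors, FPKM with and without median centring, pseudocounts of 0.1 and 1, no filter or a mean of at least 5 CPM, a 1.5-fold rule, named symbols only, leaving out mitochondrial and hemoglobin genes, unmatched random lists and lists without their most deviating member. Added after seeing the data were lowess corrections (span 0.3, statsmodels 0.14.6) of the log2 ratio on the length of the longest annotated transcript alone, then on length and GC content together, and a count without genes that overlap another counted model by at least 1 bp. Against TMM, total-count scaling shifts log2 ratios by -0.07 and DESeq2 factors by 0.0036 before the pseudocount, and low genes by less.

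The steps were tested on simulated counts for 12559 genes drawn with the real means and depths. Counting noise alone brought 1 of 12359 unchanged genes to 2-fold, and 99.0% of 100 genes simulated at 4-fold were recovered. Of the intervals 95.5% held the true ratio, and 3.67% of 300 unchanged lists lay outside the 2.5 to 97.5 percentiles. The counts behind these values held no spread between mice, no length or GC trend and no shared variation of list members. They therefore check the steps under counting noise only. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.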

Results

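Gene expression was measured by RNA sequencing of total RNA from the gastrocnemius, a calf muscle, of mice. There were 2 libraries, 1 in each group. The control library came from TECRLflox/flox mice, which carry the conditional Tecrl allele. The other came from TECRLscko mice, in which Cre expressed from the Pax7 locus deletes Tecrl in satellite cells, the stem cells of skeletal muscle. The study was set up around muscle repair, and the labels name no injury, time point or number of mice behind a library. The control library held 19281017 counts and the TECRLscko library 16946124 counts over 34745 genes. At least 10 counts were reached by 13526 genes in the control library and by 13366 genes in the TECRLscko library. The comparison asks how gene expression in the muscle differs when Tecrl is deleted from satellite cells. With 1 library per group there was no replicate to measure the spread between mice, so no p-value is given, every interval below covers counting error only, and every difference is between these 2 libraries.

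Tecrl (ENSMUSG00000049537, chromosome 5, 83278145 to 83355195, GRCm38, protein-coding), the targeted gene, had 3 counts in the control library and 4 counts in the TECRLscko library. Its TECRLscko to control ratio was 1.59, with an exact 95% interval of 0.269 to 10.9. At this depth neither a loss nor a gain of Tecrl was detectable in whole muscle, and the deletion could not be checked from these counts. Tecr, the related enoyl-CoA reductase of very long chain fatty acid elongation, was 1.38-fold lower in the TECRLscko library (95% interval 1.33 to 1.44), at 241 against 333 CPM, the count normalized to library size; its log2 ratio of -0.47 came to -0.23 after a correction for transcript length and GC content. Pax7, the satellite cell transcription factor whose locus drives Cre, was 1.56-fold higher (1.10 to 2.24), on 76 against 58 counts. Egr2 (ENSMUSG00000037868, chromosome 10, 67535475 to 67542188), an early growth response transcription factor, had 21 counts in the TECRLscko library against 4 in the control, a ratio of 6.26 with an interval of 2.11 to 25.1. Egr2 lay under the expression filter of a mean of 1 CPM and is therefore outside the gene counts given here. Egr1 was 1.33-fold lower in the TECRLscko library (1.09 to 1.62). Egr3, with 8 counts against 10, and Egr4, with 0 counts in both libraries, were too low to give a direction.

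The TECRLscko library held more message from slow, oxidative fiber genes and from the mitochondrial genome, and less from glycolytic genes. All 14 slow fiber genes were above the control, 10 of them by at least 1.5-fold, with a median log2 ratio of 0.79. They included Myh7, the slow myosin heavy chain (1.06), the slow troponins Tnnt1 (1.07), Tnnc1 (0.98) and Tnni1 (0.84), slow tropomyosin Tpm3 (1.03) and the slow calcium pump Atp2a2 (0.86), while myoglobin, Mb, stood at 0.33 and Myh7b, on 140 against 68 counts, at 1.18. All 13 mitochondrially encoded genes were above the control, 10 by at least 1.5-fold (3 after the correction for length and GC content), with a median of 0.70 and a range from 0.24 for mt-Co3 to 1.09 for mt-Nd6. Among 15 fast fiber genes the median was -0.28: Casq1 stood at -0.44, Tnnt3 at -0.37 and Atp2a1 at -0.12, whereas the fast myosins Myh2 (0.70) and Myh1 (0.39) were above the control and Myh4, the most abundant of them, stood at -0.01.

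Glycolysis genes had a median of -0.35, with 14 of 15 below the control and 3 at least 1.5-fold lower (none after that correction). These 3 were the phosphoglycerate mutase Pgam2 (-0.64), the glucose transporter Slc2a4 (-0.60) and triosephosphate isomerase Tpi1 (-0.59); the muscle enolase Eno3 stood at -0.57 and the aldolase Aldoa at -0.25. Nuclear-encoded genes of oxidative phosphorylation did not go with the mitochondrial genome: none of 30 reached 1.5-fold in either direction, and their median was -0.15. The medians of the slow fiber and the mitochondrially encoded genes lay above all 10000 random lists matched on expression, a percentile of 100, and the glycolysis median lay below all of them. The fast fiber list lay at the 0.07 percentile and the oxidative phosphorylation list at the 4.21 percentile. The mitochondrial genome took 17.01% of the counts in the control library (95% Wilson interval 16.99 to 17.03) and 23.1% in the TECRLscko library (23.05 to 23.09).

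**Figure D1:**
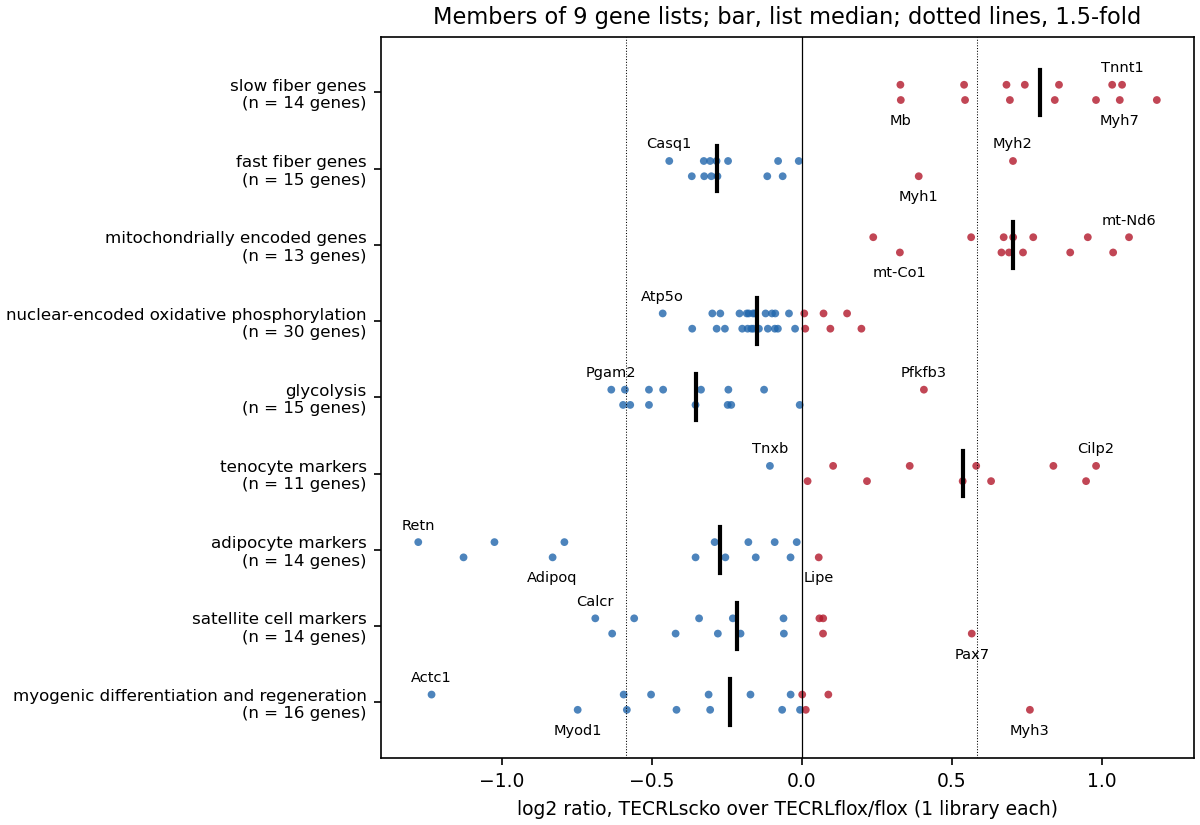
Log2 ratio of TECRLscko over TECRLflox/flox (horizontal axis, 1 library each) for each member past the filter of 9 gene lists; points are genes, red above and blue below the control, black bars are list medians and dotted lines mark 1.5-fold. All 14 slow fiber and all 13 mitochondrially encoded genes lie above 0, and 14 of 15 glycolysis genes lie below it.

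Tendon genes were also higher in the TECRLscko library. Lists of fat cell and muscle regeneration genes had medians slightly below the control, with most members within 1.5-fold, and both lay inside the random spread after a correction for transcript length and GC content (2.97 and 4.66 percentile). Of 11 tenocyte markers 10 were above the control and 4 by at least 1.5-fold, with a median of 0.54 (99.97 percentile). Cilp2 (0.98), Kera (0.95), Tnmd (0.84) and Fmod (0.63) were those 4, while Scx, the tendon transcription factor, stood at 0.02. Of 14 adipocyte markers 5 were at least 1.5-fold lower and none higher, with a median of -0.27 (0.55 percentile): resistin, Retn, stood at -1.28, adipsin, Cfd, at -1.13, Cidec at -1.02, adiponectin, Adipoq, at -0.83 and Cebpa at -0.79. The abundant Fabp4 (-0.18) and Car3 (-0.02) of the same list were close to the control. Among 16 genes of myogenic differentiation and regeneration the median was -0.24 (0.60 percentile). The fetal actin Actc1 (-1.23) and the myogenic factors Myod1 (-0.75) and Myog (-0.59) were at least 1.5-fold lower, and embryonic myosin Myh3 (0.76) was at least 1.5-fold higher.

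Satellite cell markers had a median of -0.22 over 14 genes (2.02 percentile), with the calcitonin receptor Calcr (-0.69) and Chrdl2 (-0.63) at least 1.5-fold lower, Myf5 at -0.42 and Pax7 at 0.57. Feedback genes of the ERK pathway had a median of -0.28 over 11 genes (0.61 percentile), and the phosphatases Dusp1 (-1.06) and Dusp4 (-0.78) were at least 1.5-fold lower. Antigen presentation genes had a median of -0.28 over 11 genes (0.33 percentile), with H2-Ab1 at -0.44, H2-D1 at -0.33 and no member at 1.5-fold. Fibroblast and fibro-adipogenic progenitor markers had a median of -0.20 over 15 genes (1.96 percentile), with Ly6a (-0.75), Hsd11b1 (-0.65) and Cxcl14 (-0.63) at least 1.5-fold lower and the abundant Dcn at -0.13. Endothelial markers had a median of -0.21 over 15 genes (1.41 percentile), none at 1.5-fold and Gpihbp1 at -0.54. Schwann cell markers had a median of -0.26 over 9 genes (2.15 percentile). Of these, 2 were above the control, 1 of them at least 1.5-fold higher (0.93), and none was at least 1.5-fold lower. Genes of the sarcomere and Z-disc had a median of 0.21 over 16 genes (99.23 percentile). Its 5 members at least 1.5-fold higher, of which 1 was so after the length and GC correction, included Xirp2 (0.92), nebulin, Neb (0.87), titin, Ttn (0.81), and Ankrd2 (0.61), and skeletal actin Acta1 stood at -0.15. After the same correction the sarcomere (96.76 percentile), satellite cell (12.28), ERK feedback (5.75), antigen presentation (11.5), fibroblast (6.83), endothelial (15.2) and Schwann cell lists (9.83) all lay inside the random spread, so these medians are weak. Without their most deviating member the satellite cell, myogenic, fibroblast and endothelial lists also lay inside.

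In all, 14 of the 41 lists with at least 5 measured genes lay outside the central 95% of random lists, 4 higher and 10 lower. By chance 2.05 would, if the members of a list varied independently as in the random lists. Genes of 1 fiber or cell type can vary together between any 2 samples, so the excess over 2.05 does not measure a genotype difference. Long transcripts were relatively higher in the TECRLscko library: the median log2 ratio was -0.17 in the tenth of the genes with the shortest transcripts and 0.33 in the tenth with the longest, and the Spearman correlation of ratio with length across 12529 genes, which are not independent replicates, was 0.40. The correlation with GC content was -0.43. After a correction for both trends, added once they had been seen, 8 lists lay outside. The slow fiber (median 0.74), mitochondrially encoded (0.43), tenocyte (0.71) and glycolysis lists (-0.26) did so on the same side as before, and the erythroid (0.30), immediate early (0.27), glucocorticoid-responsive (0.13) and interferon lists (-0.18) did so after this correction but not before it. The other 10 of the 14 lists then lay inside, with the fast fiber list at the 12.49 percentile. The erythroid and immediate early lists also lay outside after a correction for length alone, and the immediate early list lay outside on the lower side with FPKM (-0.34).

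**Figure D2:**
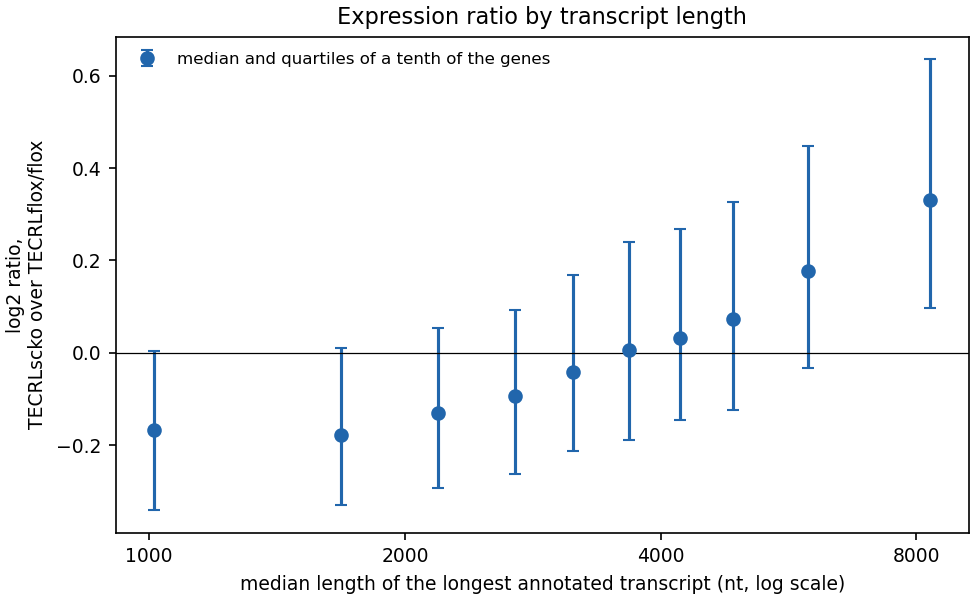
Log2 ratio of TECRLscko over TECRLflox/flox (vertical axis) against the length of the longest annotated transcript (horizontal axis, nucleotides, log scale) in 10 groups of genes of about equal number; points are medians and bars run from the lower to the upper quartile. The medians run from -0.17 in the group of shortest transcripts to 0.33 in the group of longest transcripts.

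Gene by gene, a small number of genes differed by far more than the lists did. Synpo2 (ENSMUSG00000050315, chromosome 3, 123076519 to 123236149), an actin-binding protein of the Z-disc, had 12840 counts in the TECRLscko library against 360, a 42.5-fold higher level (95% interval 38.3 to 47.4). Cish (ENSMUSG00000032578, chromosome 9, 107296026 to 107302784), a feedback inhibitor of cytokine signaling, was 20.6-fold higher (17.02 to 25.1), at 118 against 5.73 CPM. The transcription factor Zbtb20 (ENSMUSG00000022708, chromosome 16, 42875881 to 43642602) was 42.7-fold higher (31.8 to 58.8), and the kinase Nek7 (ENSMUSG00000026393, chromosome 1, 138482875 to 138620141) was 8.72-fold higher (7.75 to 9.83). Tmem127 (ENSMUSG00000034850, chromosome 2, 127247908 to 127261107), a transmembrane protein, had 72 counts against 1184 and was 13.8-fold lower in the TECRLscko library (10.9 to 17.7). The ubiquitin-conjugating enzyme Ube2l3 (ENSMUSG00000038965, chromosome 16, 17152013 to 17202649) was 5.58-fold lower (4.77 to 6.55).

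Also among the 12 highest were Fam102b, at 23.9-fold, and Gdap1, Fndc3b, Fam126a, Skil and Tnpo1, the last 5 between 5.19-fold and 6.98-fold higher. The other genes among the 12 lowest were Tspan2 (5.56-fold lower), the zinc transporter Slc30a2 (4.22-fold), Cipc, a repressor of the CLOCK protein (3.95-fold), Trmt112 (4.15-fold), monoacylglycerol lipase Mgll (3.22-fold), Znrf1 (2.96-fold), the thiamine transporter Slc19a2 (3.08-fold) and Cnih1 (2.74-fold). Some of these ratios can depend on how reads were shared out between overlapping gene models. Myh14, a nonmuscle myosin, appeared in both lists, since 1 model (ENSMUSG00000108439, chromosome 7, 44606210 to 44665497) had 662 counts against 2 and the other (ENSMUSG00000030739, chromosome 7, 44605819 to 44665503) had 181 against 810. Their sums were 843 and 812 counts, a log2 ratio of 0.30. The histone gene Hist2h2aa1 (ENSMUSG00000064220, chromosome 3, 96245497 to 96246082) had 817 counts in the control library and 0 in the TECRLscko library. Its near-identical copy Hist2h2aa2 had 128 counts against 156, so reads of the pair are uncertain. Summed with the models they overlap, Hist2h2aa1 came to a log2 ratio of -2.75, on 111 against 947 counts. In the same way Trmt112 came to -0.03, Znrf1 to -0.65 and Zbtb20 to 1.94. Such a sum also shrinks a ratio when the neighbor is unchanged, so these values alone do not show shared reads. Trmt112 itself gave only 35 of 3279 summed counts in the TECRLscko library and 173 of 4005 in the control. In the Myh14 pair, by contrast, 1 model was higher and the other lower.

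**Figure D3:**
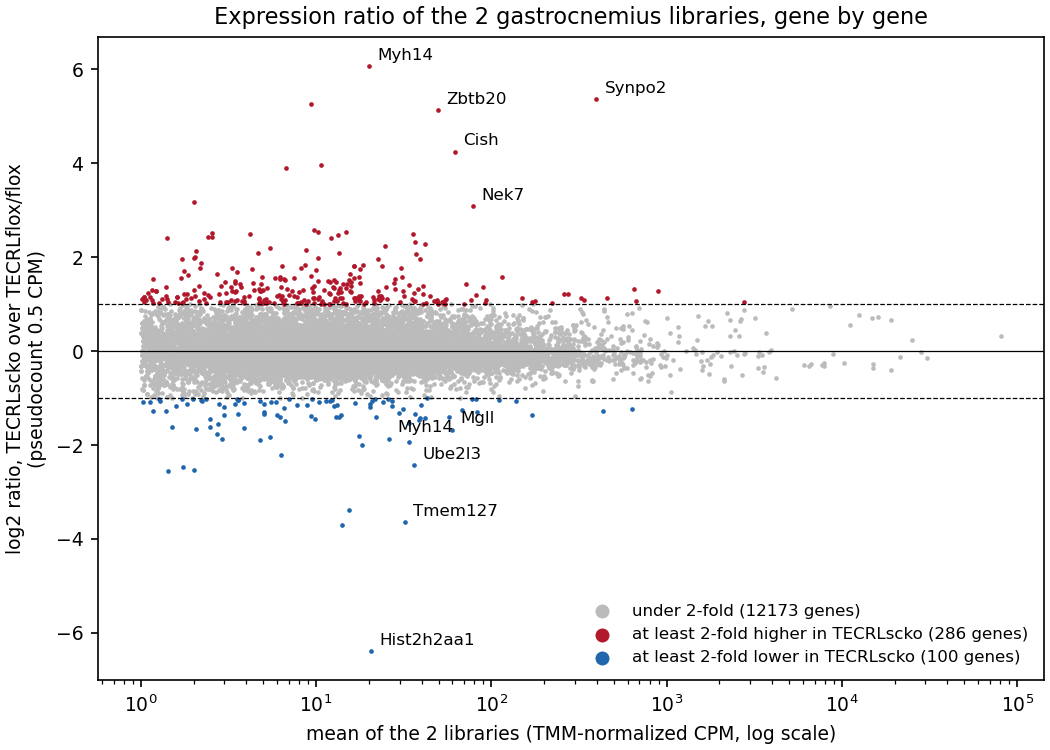
Log2 ratio of TECRLscko over TECRLflox/flox (vertical axis, pseudocount 0.5 CPM) against the mean of the 2 libraries (horizontal axis, CPM, log scale) for the 12559 genes past the filter; each point is a gene, red at least 2-fold higher and blue at least 2-fold lower in TECRLscko. Synpo2, at a log2 ratio of 5.37, is both far above the control and well expressed, and the 2 points named Myh14 are overlapping models of the same gene.

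Of the 12559 genes with a mean of at least 1 CPM, 286 were at least 2-fold higher and 100 at least 2-fold lower in the TECRLscko library, together 3.07%. The counting interval lay beyond 1.5-fold for 278 of the higher and 92 of the lower genes. The ratios of all genes had a median of -0.02 on the log2 scale and quartiles of -0.21 and 0.24. Across genes the libraries had a Pearson correlation of log2 CPM of 0.975 and a Spearman correlation of 0.974. The split differed with the deposited FPKM, where the filter, the pseudocount and the scaling differ too and 9503 genes were compared: 68 were higher and 56 lower, or 107 and 46 after median centring. After the correction for both trends 143 were higher and 95 lower.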

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

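The tests of transcript length, of length with GC content and of overlapping models were chosen after the results were seen; the others were planned. With 1 library per group, leaving out a replicate, a test in place of the size rule and the planned runs for several columns per group were not run. No paired analysis was possible because each group had 1 library and no test was made. The count of 286 genes at least 2-fold higher became 68 with FPKM, 107 with median-centred FPKM, 1161 under the 1.5-fold rule, 143 after the length and GC correction and 180 without overlapping models. The count of 100 lower genes became 56, 46 and 487 under the first 3 of these settings, 60 without overlapping models and 65 at a mean of at least 5 CPM. FPKM, the overlap setting and the higher mean compared fewer genes (9503, 8842 and 9700), and the cause was otherwise not tested. Total-count scaling gave 230 and 120 genes, and a pseudocount of 0.1 gave 371 and 142. The Pearson correlation of 0.975 across genes was 0.979 with FPKM, 0.972 and 0.977 with pseudocounts of 0.1 and 1, 0.988 with no filter, 0.966 at a mean of at least 5 CPM and 0.978 without overlapping models; the cause was not tested. The number of lists outside, 14, stayed between 10 and 14 under 12 settings, and was 8 after the length and GC correction, but its members changed. After the length correction alone 13 lay outside, 9 of them on the same side as before. With FPKM the satellite cell, adipocyte, fibroblast and endothelial lists came inside, and 4 others went outside. Without its most deviating member the satellite cell (3.67 percentile), myogenic (5.71), fibroblast (6.08) or endothelial list (3.97) came inside. The Schwann cell list came inside with no filter (8.50 percentile), without mitochondrial and hemoglobin genes (8.23), with a pseudocount of 0.1 (2.94) and at a mean of at least 5 CPM (2.52), where the satellite cell and adipocyte lists did too (5.73 and 5.90), and it had too few members with FPKM. None of these 14 list medians turned its direction. Tecrl stayed within its counting interval under all 8 settings, at log2 ratios from 0.08 to 0.44. Depth limits Tecrl, Egr2 and the immune cell lists, which rest on few counts.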

Other observations

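The tests of transcript length and GC content, of counting error, of a larger slow part of the muscle, of STAT5-induced and interferon-induced genes, and the choice of the suppressor of cytokine signaling family, of well expressed genes and of sex-linked genes came after the results were seen; the test of overlapping models was set before its value, though the neighbors of some of these genes had been viewed.

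Outside the lists already described, the metabolic lists had medians inside the random spread in the planned count analysis. The median log2 ratio of 20 genes of fatty acid oxidation and uptake was 0.11 (96.00 percentile), with lipoprotein lipase, Lpl, at 0.79 and the pyruvate dehydrogenase kinase Pdk4 at 0.65; this list lay outside with FPKM (99.81 percentile) and after the length correction (99.32). The tricarboxylic acid cycle stood at -0.02, fatty acid and triglyceride synthesis at -0.06 with Thrsp at -0.91 and Gpam at 0.72 (but at -0.27, the 0.15 percentile, after the length correction), and cholesterol synthesis at -0.16 (5.43 percentile) with Msmo1 at -0.77. Very long chain fatty acid elongation, the pathway of Tecr, had a median of -0.18 over 9 genes, with 5 below and 4 above the control. Of the 4, 1 was at least 1.5-fold higher (1.16). Glycogen genes stood at -0.09, with the glycogen targeting subunits Ppp1r3c at -0.96 and Ppp1r3a at 0.82. Excitation-contraction coupling stood at -0.08, ribosomal proteins at -0.11, neuromuscular junction genes at -0.17 with Musk at 0.59 (5.19 percentile, but 0.62 with FPKM and 1.14 at a mean of at least 5 CPM), extracellular matrix at 0.06 with periostin, Postn, at 0.79, and smooth muscle and pericyte markers at 0.07. Macrophage markers had a median of -0.08 over 17 genes, with Cd68 at -0.69 and Ccr2 at 0.70; the list lay outside with FPKM (-0.30, 0.64 percentile) and at a mean of at least 5 CPM (-0.24, 2.10 percentile). Erythroid genes stood at 0.21 (93.67 percentile), and at 0.30 (99.68) after the length and GC correction. After the same correction no member of the glycogen, extracellular matrix, fatty acid and triglyceride synthesis or macrophage lists was at least 1.5-fold higher. At least 1.5-fold lower were then 1 glycogen gene and 1 fatty acid and triglyceride synthesis gene, and no matrix or macrophage gene. Neutrophil, T and NK cell, B cell and inflammatory cytokine lists had fewer than 5 measurable members; Il6 had 4 counts against 2 and Il1b 0 against 2.

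Signaling and stress lists other than the ERK feedback genes also had medians inside the random spread in the planned count analysis. Cell cycle genes stood at 0.15, and 4 of 12 were at least 1.5-fold higher (2 after the length and GC correction). Among these 4 were Mki67, at 31 against 9 counts (1.31), and Top2a at 28 against 16 (0.74). Immediate early genes stood at 0.04, with Nr4a3 at 1.04 and Nr4a1 at -0.62; this list moved to a median of -0.34 (0.18 percentile) with FPKM and of 0.27 (99.99 percentile) after the length and GC correction, so no direction is given for it. Growth and IGF genes stood at 0.12, and atrophy genes at -0.02 with Eda2r at 0.89 and Trim63 at -0.39. The circadian clock stood at 0.16 with Clock at 0.90 and Bhlhe41 at -0.59. After the length and GC correction no atrophy or circadian gene was at least 1.5-fold higher, and 1 circadian gene was at least 1.5-fold lower. Glucocorticoid-responsive genes stood at -0.02 with Klf9 at 0.89, and this list moved to 0.13 (97.65 percentile) after that correction. Heat shock genes stood at 0.01, hypoxia genes at 0.02, antioxidant genes at 0.05, p53 targets at 0.02, ATF4 targets at 0.00 and endoplasmic reticulum stress genes at 0.07. Within these lists Chac1, a glutathione-degrading enzyme, stood at 1.58, and Xbp1, a transcription factor of the unfolded protein response, was 2.67-fold lower (95% interval 2.42 to 2.95). Among other genes with a mean of at least 50 CPM, Cited2 was 2.59-fold, Hspb6 2.49-fold and Fhl1 2.42-fold higher, and Mybph was 2.59-fold, Pkdcc 2.47-fold and the spermine oxidase Smox 2.43-fold lower in the TECRLscko library. Both libraries held Y-linked message, with Ddx3y at 538 and 1025 counts and Eif2s3y at 555 and 631, while Xist had 2 and 0.

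Slow fiber and mitochondrially encoded genes were higher in the TECRLscko library. The trend toward long transcripts of low GC content was argued against as the whole cause, because both medians stayed above all random lists after the correction, at a percentile of 100 each, though that of the mitochondrial genes went from 0.70 to 0.43. A larger slow, oxidative part of the muscle in the TECRLscko sample, from dissection or from a difference between mice, may also account for it, and then nuclear-encoded oxidative phosphorylation genes should be higher as well. That rise was not seen: 24 of the 30 genes lay below the control before the correction. Their corrected median of -0.055 lay at the 30.1 percentile, inside the random spread. Under the rule, written after the results were seen, a median inside that spread decides nothing. A larger slow part was therefore neither shown nor excluded. The test does not separate dissection from genotype, since a larger slow part from either predicts the same rise. With 1 library per group a larger slow part from dissection or between mice cannot be told apart from a genotype difference. The higher tenocyte markers, with Tnmd at 0.84, are a further sign that the composition of the samples could differ.

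There were 28 genes at least 4-fold different at a mean of at least 5 CPM, 21 higher and 7 lower in the TECRLscko library. Overlapping gene models could account for some of them. Of the 28, 10 (35.7%) overlapped another counted model, against 29.2% of the genes under 2-fold, and only those 10 could change in a sum. When the counts of overlapping models were summed, 5 of the 28, or 17.9%, all among those 10, came under 2-fold. Among them were Myh14 and Gm20716, which had 311 counts against 0 while the model Dpm1 that it overlaps had 280 against 686. A sum with an unchanged neighbor also shrinks a ratio, so not all 5 need reflect shared reads. Synpo2, Nek7 and Tmem127 overlap no other counted model. After the length and GC correction 100% of the 27 genes with a value stayed at least 2-fold different, the smallest being Smek2 at a log2 ratio of 1.69. Because the genes were picked at 4-fold and the correction was small beside that, this test had little room to come out otherwise. Counting error was argued against: of the 9700 genes with a mean of at least 5 CPM it alone would bring 0.000166 even to 2-fold. In the test planned first, the interval of 0% of the 28 genes reached 1.5-fold. That test decides nothing, because picking genes at 4-fold already holds the interval beyond 3.28-fold. A hypothesis for such genes is a difference between the mice or samples themselves, which remained untested without replicates.

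Cish (20.6-fold), Socs1 (11.6-fold, on 78 against 8 counts), Socs3 (3.29-fold) and Socs2 (2.62-fold), feedback inhibitors induced by cytokine receptors, were higher together. Of the rest of the family Socs4 was 1.48-fold higher (95% interval 1.18 to 1.85), but its log2 ratio of 0.54 came to -0.03 after the length and GC correction. Socs5 stood at a log2 ratio of -0.04, Socs6 at -0.16 and Socs7 at 0.07, while Bcl6, which STAT5 represses, was 2.04-fold lower. Among the 4 genes the length and GC correction lowered only Socs2, from a log2 ratio of 1.34 to 1.20, and their median stood at 2.26 after it. The 4 genes were chosen after their high ratios were seen, so this test had little room to come out otherwise. A candidate explanation is cytokine or growth hormone signaling through STAT5 that was stronger in the TECRLscko sample at the time of sampling. The wider rise it predicts was looked for and not seen: 10 other STAT5-induced genes had a median of -0.10 (24.8 percentile), with Igf1 at 0.42, 16 interferon-induced genes had -0.11 (13.7 percentile, and 1.95 after the correction), and 11 STAT3-induced genes had -0.05. The range in which the STAT5 and interferon tests decide nothing was widened after these percentiles had been seen, and since members of both lists go both ways neither source is excluded.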
